A study of Mus musculus with 2 samples.

How the data were processed

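H3K9ac, acetylation of lysine 9 on histone H3, was measured by chromatin immunoprecipitation and sequencing in kidneys of C57BL/6-derived (B6NCrl) mouse embryos at embryonic day 15.5. The series held 1 group of 2 biological replicates. Per the labels, replicate 1 was made from the kidneys of 78 embryos and replicate 2 from those of 62, with males and females mixed in each. The replicates were therefore separate pools of animals, and no second tissue, stage or mark was compared. A between-group test was not possible with 1 group.

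Peak lists on the mouse genome build mm10 (GRCm38) were the only measurements used. Per the readme deposited with the samples, each replicate's list was made from that replicate's own alignment and a control, the pooled list from the alignments of both replicates and their controls, and the replicated list from both replicates. The aligner, the peak caller, its threshold and the rule behind the replicated list were not given in the sources used here. Every row of the deposited replicated list was also a row of the deposited pooled list.

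The deposited lists were in narrowPeak format and held no header line. The deposited signal value of a peak was taken as a ratio, its enrichment over the control, since the readme names a control for each list and all values exceeded 1. The deposited −log10 of the p-value and −log10 of the q-value were used as given, and the lowest −log10 p-value was 2.01 in the replicate 1 and pooled lists and 2.04 in the other 2. The deposited score, which runs to 1000, was not used further. These values are the authors' own per peak, and they served to describe, rank or filter peaks within 1 list. The signal value at promoters of X was also tested, against autosomal lists matched on CpG content. Peak lists hold no read counts, so the sequencing depth of each replicate is unknown, and a longer list can come from deeper sequencing. Intervals on shares of peaks are Wilson 95% intervals and cover counting error only.

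Genes, transcript starts and exons came from GENCODE M21 (Ensembl 96) on the same build, and promoter sequence from the GRCm38 assembly. The 21938 protein-coding genes of chromosomes 1 to 19, X and Y were tested. A promoter was called marked when a peak overlapped the window of 1000 bp on either side of any annotated start of the gene. Peaks were assigned to the promoter window, exons, introns or the space between genes by their summit. A distal peak lay over 2500 bp from every annotated transcript start. Domains were made by merging replicated peaks within 1000 bp. A gene's domain was the widest that met its promoter window, and its distal count was the number of distal peaks with a summit within 100000 bp of one of its starts. Neighbouring genes share peaks under these definitions, so the values of genes in 1 cluster are not independent.

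Before the data were examined, 28 gene lists, the tests, the named-gene rule and most alternatives were fixed. The lists cover kidney compartments (nephron progenitors, early nephron, ureteric bud and collecting duct, renal stroma, podocytes, proximal tubule, loop of Henle and distal tubule), other cells of the organ (endothelium, macrophages and leukocytes, erythroid cells), neighbouring or unrelated tissues (adrenal gland and gonad, neurons, heart and skeletal muscle, hepatocytes, epidermis, spermatogenesis, photoreceptors, chemosensory receptors), signalling pathways (Wnt, Notch, BMP and Hedgehog), 3 Hox lists, housekeeping, cell cycle and imprinted genes, and genes linked to congenital anomalies of the kidney and urinary tract. Some genes stand in more than 1 list. Of the listed symbols, 1 (Ahsp) had no match in the annotation and 4 imprinted members (H19, Kcnq1ot1, Meg3, Airn) were noncoding, so these were left out of the list tests.

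Shares of peaks common to both replicates were counted at an overlap of at least 1 bp and set beside 100 seeded random placements on the same chromosomes. Marked list members were compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 28 lists. The chromosome X genes were compared with autosomal genes by the same test. The median domain width of marked members was ranked among 10000 random lists of as many marked genes, for lists with at least 5 marked members. The mean distal count was ranked among 10000 random lists of as many protein-coding genes. Both gave two-sided permutation p-values, adjusted over the lists tested, and calls used an adjusted p of 0.05. The smallest p the random lists can give is 2e-04, and the smallest the placements can give is 0.0198. Genes are not independent replicates, so every p describes these 2 libraries and not the spread between animals. An adjusted p over all genes does not arise, because no test was run per gene.

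The named genes were chosen by rule. Per list, up to 4 members with the highest signal value of a replicated promoter peak and up to 4 members without one, in alphabetical order, were named. The 10 genes with the widest domains, the 10 with the highest promoter signal and the 10 with the most distal peaks were added. Per replicate, the 5 with the strongest promoter peak among genes marked in that replicate's list alone were added too. Any member of the nephron, ureteric, stromal, podocyte and Hox lists could also be named. The rule took 283 genes. Genes named outside it are said to have been chosen after their values were seen.

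Alternatives covered the overlap that counts as shared, a q-value of 0.01 or lower, a signal value of 4 or more, windows of 500 and 2500 bp, the outermost start only, the pooled list, each replicate's own list, lists of equal length, merging distances, a distal reach of 50000 bp, random lists from marked genes, and 10000 random lists matched on promoter CpG content. CpG content was the CpG count per 100 bp within 500 bp of a start, taken at the gene's most CpG-rich start and divided into 10 groups. Added after the data had been seen were a restriction to genes with no other coding start within 2000 bp, a restriction to genes with at least 90% of their promoter 32-mers found once in the genome, CpG matching of the width and distal tests and of chromosome X, X without chemosensory receptor genes, counting each domain once, and a looser overlap rule for the replicated list.

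Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The list tests were checked on simulated lists of 20 genes drawn from the 21938. Fisher's test called 4.5% of 200 lists with no difference at an unadjusted threshold. It called 71.0% of lists with 95% of members marked and 76.0% of lists with 25% marked. Marks for this check were drawn independently for each gene. The check therefore does not cover lists whose members share peaks or differ from other genes in CpG content. The width test called 6% of 50 unchanged lists and all lists with widths multiplied by 2. The distal test called 2% of 50 unchanged lists and all lists with 2 peaks added per gene. Peaks on unplaced scaffolds, 7 and 8 in the lists of replicates 1 and 2, 10 in the pooled and 5 in the replicated list, were counted where lists were compared with each other and entered no comparison of genes or locations. Alignments and signal tracks were not used here.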

Results

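H3K9ac, a histone mark found at active promoters and enhancers, was profiled in the mouse kidney at embryonic day 15.5, a stage at which nephrons are still being formed around the branching ureteric bud. The single group held 2 biological replicates, pools of kidneys from 78 and 62 embryos of both sexes. Replicate 1 gave 51946 peaks with a median width of 308 bp, and replicate 2 gave 42047 peaks with a median width of 364 bp. The pooled list held 59502 peaks and the replicated list 25909 peaks with a median width of 911 bp, covering 29.6 Mb. The lists give no read counts, so the depth behind each is unknown. All coordinates are on build mm10. The signal values are the authors' own, an enrichment over the control for each peak.

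The replicates were compared first, to see which H3K9ac peaks were found in both pools of embryos. The 10 strongest replicated promoter peaks were found in both replicates. Cytoplasmic actin Actg1 had the highest signal value, 36.7, followed by the chaperone Hsp90aa1 at 35.0, the histone methyltransferase Kmt5b at 33.2 and the ribosomal protein gene Rpsa at 32.6. The Actg1 peak spanned chromosome 11 from 120347203 to 120351540 and had its summit in an exon of the gene (ENSMUSG00000062825.15, 120345690 to 120348542). Adnp, Sp3, Ywhaz, Eif4h, Khdrbs1 and Atxn2l made up the rest of the 10 highest, with values down to 30.9.

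Over all peaks, 51.1% of replicate 1 peaks shared at least 1 bp with a replicate 2 peak (Wilson 95% interval 50.7 to 51.5), and 63.9% of replicate 2 peaks with a replicate 1 peak (63.4 to 64.3). Random placement gave means of 2.00% and 2.47%. All peaks in the highest 10% by signal value were shared in either direction, against 19.4% of replicate 1 peaks and 29.6% of replicate 2 peaks in the lowest 10%. The shares moved with the overlap rule and the threshold, from 37% and 45.8% with 50% of both peaks required to 87.3% and 82.9% among peaks with a signal value of 4 or more.

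**Figure D1:**
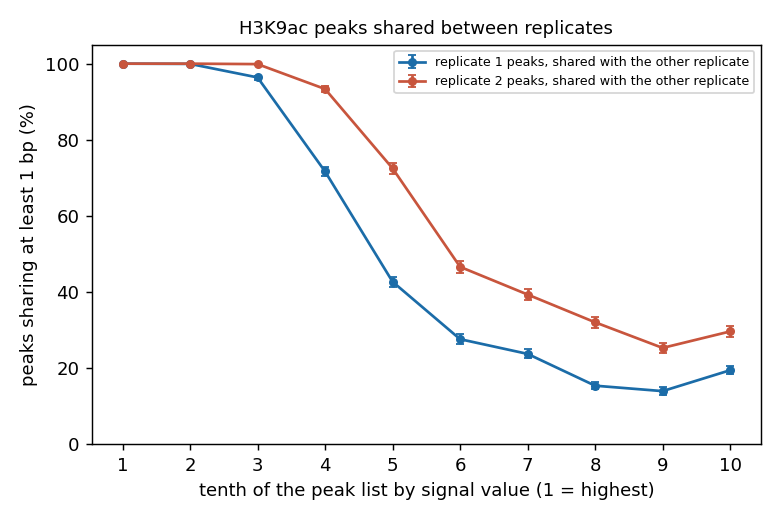
Percent of each replicate's H3K9ac peaks that share at least 1 bp with a peak of the other replicate (vertical axis), by group of 10% of the list from the highest to the lowest signal value (horizontal axis); lines join the points of 1 replicate and bars are Wilson 95% intervals. The share is 100% in the highest group of both replicates and falls to 14.0% for replicate 1 and 25.3% for replicate 2 in the group before the lowest.

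At the level of promoters the replicates were closer than at the level of peaks. Replicate 1 marked 65.2% of the 21938 protein-coding genes and replicate 2 marked 64.1%, a mean of 64.7% ± 0.777 (SD, n = 2). Both lists marked 13706 genes, 600 genes were marked in replicate 1 alone and 359 in replicate 2 alone. Among the genes marked in both, 99.5% were also marked in the replicated list, against 22.2% and 20.6% of those marked in 1 replicate. Among genes marked in replicate 1 alone, signals were highest at Igflr1, C2cd4d and the class II histocompatibility gene H2-Ab1. The matrix gene Thbs4 and the lymphoid transcription factor Ikzf3 came next. Among genes marked in replicate 2 alone, signals were highest at Exoc3l, Gm8773, Ppp2r2c, Stum and the slow muscle troponin Tnni1. Their values in the list that held them ran from 10.1 at Igflr1 to 5.75 at Ikzf3, and from 19.6 at Exoc3l to 5.26 at Stum and Tnni1. Igflr1 and Exoc3l had the start of another coding gene within 2000 bp. All replicate 2 peaks with a signal value from 13.4 to 35.4 overlapped a replicate 1 peak. The Exoc3l peak was therefore found in both replicates, and only its reach into the promoter window differed. Igflr1 and C2cd4d fell in a range of replicate 1 signal values, 7.30 to 11.5, in which 99.9% of peaks were shared. The replicated peaks of Exoc3l, Igflr1 and C2cd4d had summits 1784, 1924 and 1265 bp from the gene's nearest start. A gene in 1 list alone is not shown to differ between the pools. With a signal value of 4 or more the counts became 385 and 543, and with lists of equal length 460 and 461.

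The replicated list was then set against the lists it derives from. It held 43.5% of the pooled peaks. Of its peaks, 16750 (64.6%) were covered over at least 50% of their length by a single peak of each replicate. Every pooled peak covered in this way was in the replicated list. Coverage by several peaks of a replicate together was not counted. In all, 22380 replicated peaks (86.4%) shared at least 1 bp with both replicates. The other 3529 replicated peaks overlapped a peak of replicate 1 only (2043), of replicate 2 only (1270) or of neither (216). These 3529 had a median signal value of 3.12, against 7.34 for peaks found in both. Of them, 64.9% lay over 1000 bp from any transcript start along their whole length.

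H3K9ac was concentrated at promoters. Of the 25904 replicated peaks on placed chromosomes, 18196 (70.2%, Wilson 95% interval 69.7 to 70.8) had their summit within 1000 bp of an annotated transcript start, 10.8 times the 6.49% ± 0.158 (SD over 100 placements) of randomly placed peaks. Introns held 14.5% of summits against 40.4% of placed peaks, the space between genes 10.9% against 49.7%, and exons 4.37% against 3.45%. Each of the 4 shares lay outside all placements (permutation p = 0.0198, two-sided, the smallest possible). Promoter peaks were also the strongest, with a median signal value of 8.90 against 3.35 in introns and 3.75 between genes. The promoter share was 48.2% and 56.0% in the lists of replicates 1 and 2 and 42.1% in the pooled list. Exon shares lay below placement with a window of 2500 bp and among peaks with a signal value of 4 or more.

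The marking of promoters was compared between gene lists and all other protein-coding genes, of which 63.1% carried a replicated peak in the promoter window. The lists of the developing nephron were marked nearly throughout. Nephron progenitor genes were marked in 19 of 20 cases (Fisher's exact test, two-sided, adjusted p = 0.00374 over the 28 lists). The growth factor Fgf20 (signal value 19.4), the transcription factors Pax2 (17.8) and Sall1 (17.1) and the ureteric chemoattractant Gdnf (14.8) were highest, and Six2, the regulator of progenitor renewal, had 8.52. The Pax2 peak (ENSMUSG00000004231.15, chromosome 19, gene from 44756045 to 44837871) ran from 44754879 to 44763474 with its summit in an exon. Meox1 was the member without a replicated peak, and Fgf20 and Crym had another coding start within 2000 bp. Early nephron genes, expressed as progenitors turn into epithelium, were marked in all 18 cases (adjusted p = 0.00101, exact), with Notch2 at 24.8, its ligand Jag1 at 15.3, Pax8 at 14.4 and Irx3 at 12.2. Wnt4 (7.78) and Lhx1 (10.8) belonged to the same list.

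Ureteric bud and collecting duct genes were marked in 19 of 21 cases (adjusted p = 0.0177, exact), led by the signalling inhibitor Spry1 (20.0), Hoxb7 (18.3), Emx2 (13.6) and Etv5 (11.3). The Hoxb7 value belongs to a peak shared with Hoxb5, Hoxb6 and Hoxb8, with its summit 3462 bp from the nearest Hoxb7 start. The receptor gene Ret, which drives branching, had a signal value of 5.84. The unmarked members were the water channel gene Aqp2 and Elf5. The ureteric call ended at a signal value of 4 or more (adjusted p = 0.141, exact) and among unique promoters (0.145). Among unique promoters 89.5% of the ureteric genes were still marked, against 71.3% of the others. Podocyte genes, active in the filtering epithelium of the glomerulus, were marked in 15 of 17 cases (adjusted p = 0.0482, exact), with Cd2ap at 22.6, Actn4 at 19.7, Foxc2 at 18.0 and Tcf21 at 14.1. The podocyte call ended at the outermost start and at a signal value of 4 or more (adjusted p = 0.0942 for each, exact) and among unique promoters (0.192), and the share lay below CpG-matched random lists (88.8%). Among unique promoters the podocyte share was still 88.2%, against 71.3% of the others. The unmarked podocyte members were the slit diaphragm genes Nphs1 and Nphs2. Nphs1 met a peak in each replicate's own list, of signal value 2.28 and 3.51, and has another coding start within 2000 bp. Renal stroma genes were marked in 19 of 23 cases (adjusted p = 0.0607, exact) and endothelial genes in 14 of 16 (adjusted p = 0.0708, exact), which did not pass. The stromal transcription factors Nr2f2 (22.5), Pbx1 (21.4), Nr2f1 (18.3) and Meis2 (16.4) were marked, as was Foxd1 (10.3), while Dcn, Lum, Postn and the renin gene Ren1 were not. In endothelium Egfl7 (13.4, with another coding start within 2000 bp), the receptor Kdr (7.49), Cldn5 (7.10) and Ehd3 (6.87) were marked, and Plvap and Tie1 were not. The congenital kidney anomaly list was marked in 28 of 29 cases (adjusted p = 0.000235, exact), with Foxc1 at 23.0, Nrip1 at 21.7, Pbx1 at 21.4 and Six5 at 19, and the urothelial gene Upk3a was its unmarked member.

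Proximal tubule genes, which encode transporters and metabolic enzymes, were marked in 10 of 24 cases (41.7%, adjusted p = 0.0420, exact). The bicarbonate transporter Slc4a4 (10.8), Ggt1 (10.4, with another coding start within 2000 bp), the endocytic receptor Lrp2 (8.55) and Hnf1a (5.94) were marked. Aldob, the water channel gene Aqp1, Cubn and Fbp1 were not. Of these, Aldob, Aqp1 and Fbp1 met a peak in replicate 1's own list (3.39, 2.09 and 3.13) and were marked in the pooled list. Loop of Henle and distal tubule genes were marked in 9 of 18 cases (adjusted p = 0.328, exact), without Bsnd, Cldn16, Kcnj1 and Klk1. Ppp1r1a had 6.94, Tfap2b 6.71, Egf 5.39 and Cldn10 5.13, and Egf and Cldn10 were not marked at the outermost start. This list passed below the others at the outermost start (16.7% against 59.5%, adjusted p = 0.000795, exact). It also passed below them at a signal value of 4 or more (22.2% against 59.3%, adjusted p = 0.00416, exact). The proximal tubule share was 62.5% in replicate 1 and 45.8% in replicate 2, a mean of 54.2% ± 11.8 (SD, n = 2), and its adjusted p was 0.831 and 0.0965 in their own lists by the same exact test. It was 0.418 in the pooled list, and random lists matched on CpG content had means of 45.2% for the proximal tubule and 41.6% for the loop of Henle and distal tubule.

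Lists of blood cells and of other organs lay below the remaining genes. No hepatocyte gene of 19 was marked (adjusted p = 8.03e-08, exact), Afp, Ahsg, Alb and Apoa1 among them. Spermatogenesis genes were marked in 1 of 14 cases (adjusted p = 0.000193, exact), namely Zpbp (8.62), which has another coding start within 2000 bp, and Acrv1, Akap4, Ldhc and Odf1 were unmarked. Heart and skeletal muscle genes were marked in 3 of 19 cases (adjusted p = 0.000193, exact), namely Ckm (7.65, with another coding start within 2000 bp), Ryr2 (7.03) and Actn2 (4.08), and epidermal genes in 2 of 13 (adjusted p = 0.00163, exact). The epidermal pair, the keratin genes Krt10 (11.1) and Krt1 (8.08), was marked at an internal start and not at the outermost one. Macrophage and leukocyte genes were marked in 3 of 15 cases (adjusted p = 0.00209, exact), namely Coro1a (6.40), Aif1 (3.90) and Cd68 (2.97, with another coding start within 2000 bp), and the complement genes C1qa, C1qb and C1qc were unmarked. The macrophage call ended with the pooled list (adjusted p = 0.0577, exact). Adrenal and gonadal genes were marked in 4 of 16 cases (adjusted p = 0.00526, exact), with Dazl at 5.52 and the steroidogenic regulator Nr5a1 at 2.89, and without the steroidogenic enzymes Cyp11a1, Cyp11b1 and Cyp17a1.

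Erythroid genes were marked in 4 of 13 cases (adjusted p = 0.0263, exact), namely Klf1 (11.1), Gypa (5.39), Tal1 (4.82) and Epor (3.77), and the globin gene Hba-a1 and the regulator Gata1 were unmarked. The erythroid call ended at the outermost start (adjusted p = 0.0566, exact), among unique promoters (0.147) and without neighbouring starts (0.0631), and the 30.8% marked lay above CpG-matched random lists (23.7%). Photoreceptor genes were marked in 5 of 16 cases (adjusted p = 0.0236, exact), with Rom1 at 12.9 (another coding start within 2000 bp), Nrl at 5.26, Cngb1 at 4.84 and Opn1sw at 4.22, and without Crx. Neuronal genes were marked in 7 of 20 cases (adjusted p = 0.0236, exact), with Elavl4 at 9.07, the glutamate transporter Slc17a7 at 6.87, Camk2a at 3.75 and Isl1 at 3.67, and without Gad1, Gad2, Elavl3 and Neurod1. Neuronal shares were 55% and 50% in the replicates' own lists, where the adjusted p was 0.380 and 0.243 by the same exact test, and the call also ended with the pooled list (0.816), a window of 2500 bp (0.108) and without neighbouring starts (0.0740). Chemosensory receptor genes, which serve smell and pheromone sensing, were marked in 2 of 1464 cases, Vmn1r4 (10.3, with another coding start within 2000 bp) and Olfr94 (3.26). The share of 0.137% compared with a mean of 2.10% in random lists matched on CpG content (permutation, adjusted p = 0.00187, from the smallest p possible).

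Genes active in most dividing cells and genes of signalling pathways were marked nearly without exception. All 20 housekeeping genes (adjusted p = 0.000711) and all 21 cell cycle genes (adjusted p = 0.000439) were marked by the exact test, with Ywhaz (31.7) and Actb (29.2) highest among the former and E2f1 (15.8), Aurka (15), Mcm6 and Top2a (14.8 each) among the latter. Aurka has another coding start within 2000 bp. All 15 Notch genes (adjusted p = 0.00374, exact) and all 13 Wnt genes (adjusted p = 0.00545, exact) were marked, led by Maml1 (27.4), Notch2 (24.8), Tcf7l1 and Tcf7l2 (19.8 each). Of the BMP and Hedgehog genes 19 of 20 were marked (adjusted p = 0.00374, exact), with Smad6 (24.9), Smo (23.9), Smad5 (22.5) and Ptch1 (21.9) highest and the ligand gene Shh unmarked. Of the imprinted genes 14 of 15 were marked (adjusted p = 0.0223, exact), with Gnas (24.1), Grb10 (16), Igf2r (14.5) and Mest (11.5) highest and Ndn unmarked. At the outermost start 66.7% of the imprinted genes were marked (adjusted p = 0.794, exact). The call also ended among unique promoters (0.105) and without neighbouring starts (0.0631). Among unique promoters 93.3% were still marked, against 71.3% of the others, and without neighbouring starts 90% against 58.1%.

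The Hox genes, which set position along the body axis, were marked up to group 11 in all 4 clusters. All 23 genes of groups 1 to 8 (adjusted p = 0.000193, exact) and all 10 genes of groups 9 to 11 (adjusted p = 0.0236, exact) carried a replicated peak, with Hoxd3 and Hoxd4 (23.7 each, 1 shared peak, starts within 2000 bp of another coding start), Hoxd8 (20.0) and Hoxb2 (19) highest in the former and Hoxa10 and Hoxa9 (20.6 each, 1 shared peak), Hoxd9 (19.7) and Hoxb9 (16.9) in the latter. In groups 12 and 13, 2 of 6 genes were marked (adjusted p = 0.209, exact). These were Hoxd12 (4.74) and Hoxd13 (4.37), and Hoxa13, Hoxb13, Hoxc12 and Hoxc13 were not. Among unique promoters all 10 genes of groups 9 to 11 stayed marked, against 71.3% of the others, and the call ended (adjusted p = 0.0963, exact). Random lists matched on CpG content had a mean of 93.8% marked against the 33.3% of groups 12 and 13 (permutation, adjusted p = 0.00187).

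**Figure D2:**
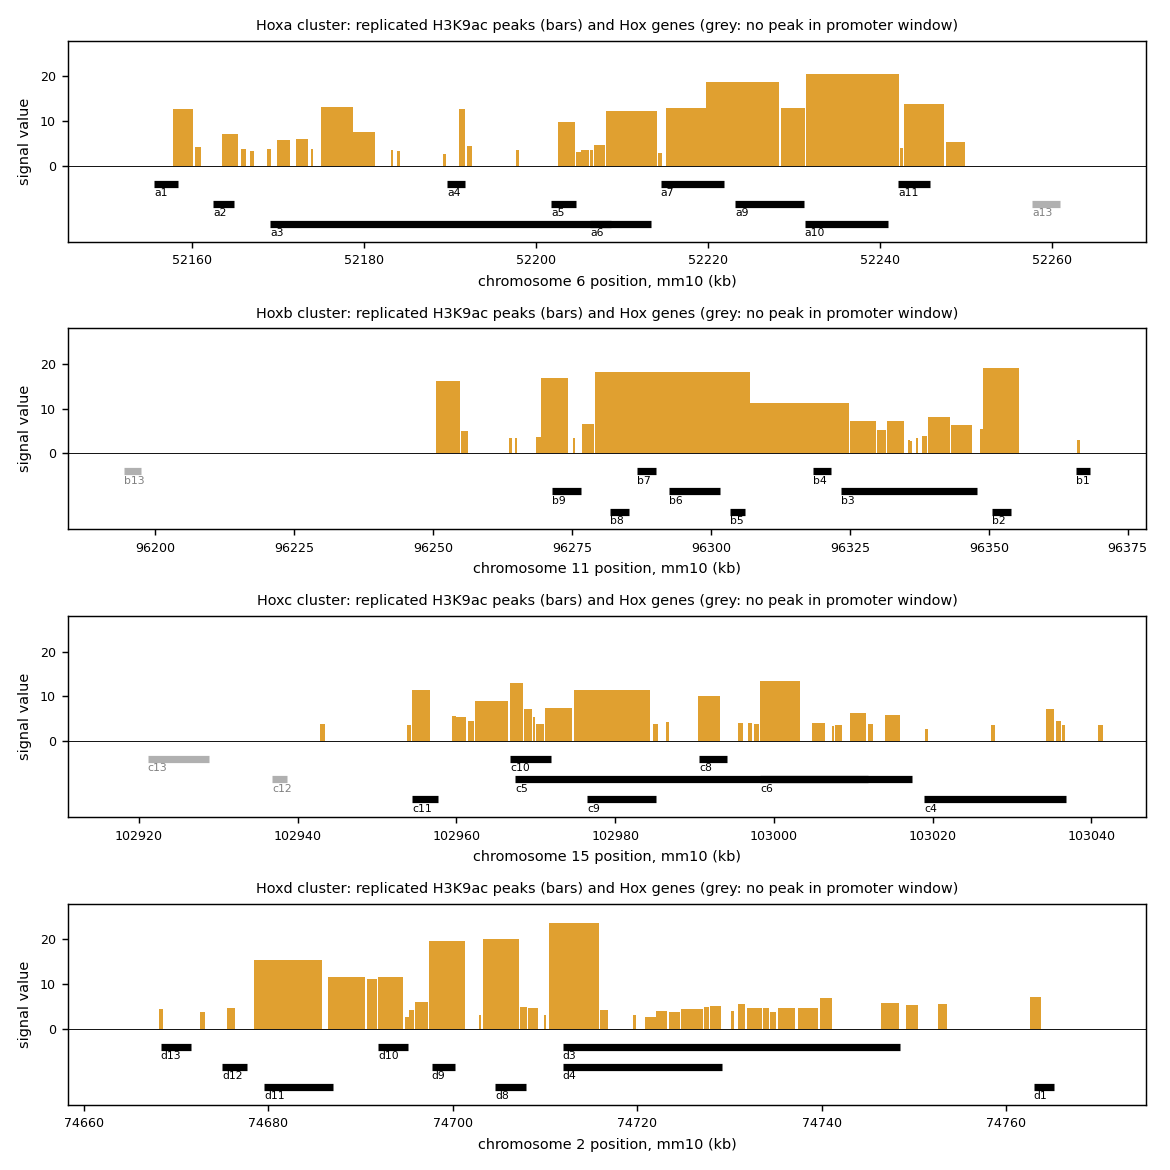
Replicated H3K9ac peaks over the 4 Hox clusters (each panel 1 cluster; horizontal axis, mm10 position in kb; vertical axis, signal value of the peak; bars span each peak). Gene bodies below are black where the promoter window held a replicated peak and grey where it did not. Hoxa13, Hoxb13, Hoxc12 and Hoxc13 are grey, and the tallest peak, at Hoxd3 and Hoxd4, has a signal value of 23.7.

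Promoter CpG content went with marking over all genes, from 0.312% of genes marked in the group of lowest content to 98.8% in the highest. Against random lists matched on it, none of the 13 lists above the other genes passed (adjusted p from 0.241 to 1), and 2 of the 13 could have passed with every member marked. Of the 11 lists below, 5 passed (adrenal gland and gonad, neurons, heart and skeletal muscle, spermatogenesis and chemosensory receptors). Renal stroma (82.6% against 66.9%, adjusted p = 0.0416, permutation) and endothelium (87.5% against 61.1%, adjusted p = 0.0149, permutation) also passed, both above. By the exact test endothelium did not pass at a signal value of 4 or more (62.5% against 59.3%). At the outermost start it did not pass either (68.75% against 59.5%, adjusted p = 0.635, exact). Renal stroma did not pass at a signal value of 4 or more (adjusted p = 0.218, exact) or among unique promoters (0.355). Both passed in replicate 2's own list (adjusted p = 0.0319 for stroma and 0.0210 for endothelium, exact).

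**Figure D3:**
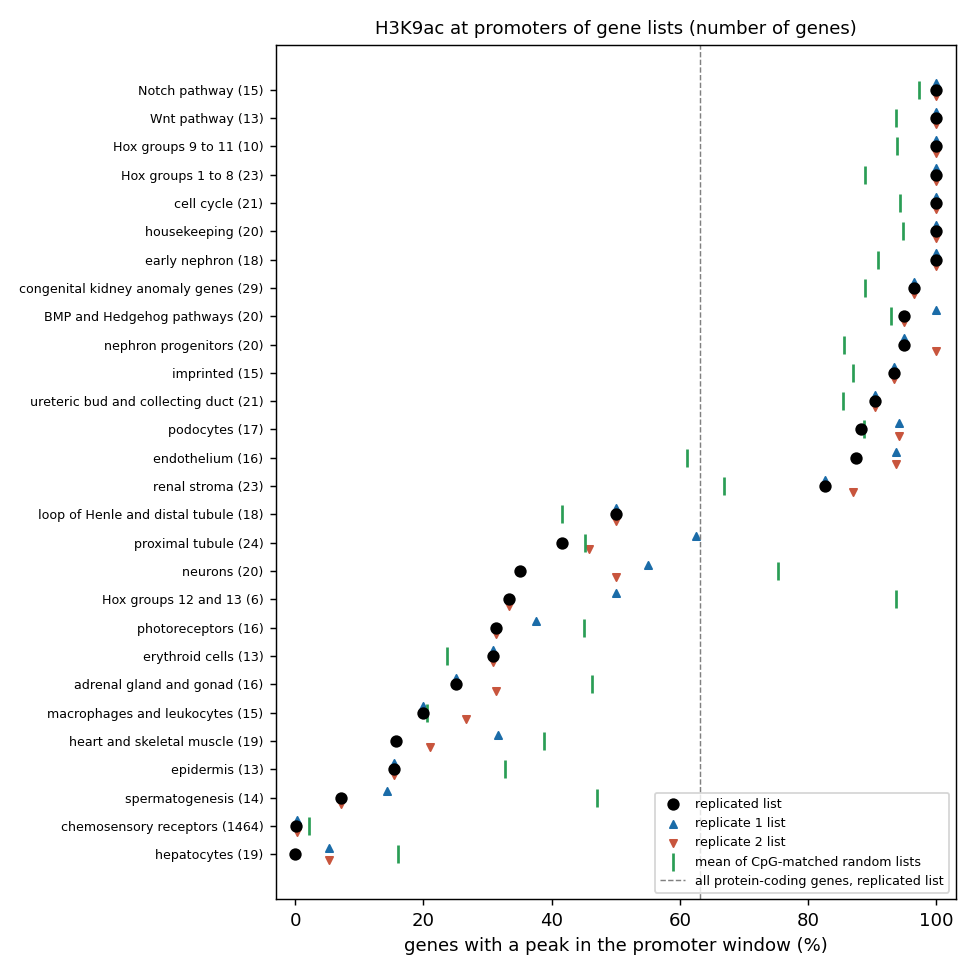
Percent of each gene list (vertical axis, number of genes tested in brackets) with an H3K9ac peak in the promoter window (horizontal axis). Black circles are the replicated list, triangles each replicate's own list, green bars the mean of random lists matched on CpG content and the dashed line all protein-coding genes (63.1%). Nephron progenitor, early nephron and ureteric lists lie at 90.5% or above, podocytes at 88.2%, loop of Henle and distal tubule at 50%, proximal tubule at 41.7% and hepatocyte genes at 0%.

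Chromosome X was compared with the autosomes because male and female embryos were pooled. On X, 410 of 948 genes were marked (43.2%, Wilson 95% interval 40.1 to 46.4), against 13439 of 20807 on the autosomes (64.6%; Fisher's exact test, two-sided, p = 7.57e-39). The progenitor gene Cited1 was among the marked X genes (5.99), and the erythroid genes Gata1 and Alas2 and the sperm gene Akap4 were among the unmarked. On Y, 3 of 183 genes were marked. They were chosen for naming after their values were seen and were Uty (3.75), Ddx3y (3.12) and Kdm5d (3.12). The difference between X and the autosomes was smaller among genes with unique promoter sequence, 59.5% against 71.8% (p = 2.10e-11, exact).

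The width of the acetylated domain at marked promoters was compared between lists. Hox genes had the widest domains. Hoxb3 to Hoxb8 shared a domain of 70060 bp on chromosome 11 (96276829 to 96346888), and Hoxa3, Hoxa5 to Hoxa7 and Hoxa9 to Hoxa11 shared one of 47417 bp on chromosome 6 (52202482 to 52249898). Hoxd9 to Hoxd11 shared a domain of 22892 bp on chromosome 2. The median width was 24439 bp for groups 9 to 11 and 14015 bp for groups 1 to 8, against 1861 bp over all marked genes (permutation, adjusted p = 0.000543 for each, from the smallest p possible). Outside the Hox clusters the widest domains of the kidney lists lay at the stromal gene Nr2f2 (25892 bp), Pax2 (18098 bp), Meis2 (17228 bp), Meis1 (14172 bp) and Sall1 (11428 bp), and Six2 had 10228 bp. The Hox medians depended on the merging distance. With only overlapping peaks merged they were 4742.5 bp for groups 9 to 11 and 5414 bp for groups 1 to 8, within 3000 bp both were 47417 bp, and with each domain counted once groups 1 to 8 had 3709 bp, all past the threshold.

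Of 19 lists with enough marked members, 10 had wider and 4 narrower domains than random lists of marked genes. The wider lists after the Hox genes were renal stroma (4762 bp, adjusted p = 0.000543, permutation), Notch (3554 bp), housekeeping (3541 bp), BMP and Hedgehog (3413 bp), Wnt (3016 bp), early nephron (2996.5 bp), cell cycle (2943 bp) and congenital kidney anomaly genes (2869 bp), all with a permutation adjusted p of 0.00823 or lower. With only overlapping peaks merged the medians of renal stroma, housekeeping and Notch genes fell to 2594, 2155.5 and 2139 bp, against 1508 bp over all marked genes, and these calls stayed. The narrower lists were photoreceptors (652 bp, adjusted p = 0.00553), loop of Henle and distal tubule (659 bp, 0.000950), neurons (889 bp, 0.0166) and proximal tubule (995.5 bp, 0.00935), each by permutation. The medians of nephron progenitors (2087 bp, adjusted p = 0.498), ureteric genes (1999 bp, 0.639), podocytes (2481 bp, 0.0960), endothelium (1687.5 bp, 0.620) and imprinted genes (2243 bp, 0.279) did not pass in the same permutation test. With peaks merged within 3000 bp, nephron progenitors (0.0128), ureteric (0.00507) and imprinted genes (0.00896) were wider, and in the pooled list nephron progenitors and ureteric genes were (0.0169 each). Nephron progenitors also passed when only overlapping peaks were merged (0.0429), and podocytes (0.0207) and imprinted genes (0.0163) when each domain was counted once. The Wnt and proximal tubule calls ended when the random lists were matched on CpG content (permutation, adjusted p = 0.0576 and 0.177), and the cell cycle call ended when only overlapping peaks were merged (0.233). The proximal tubule call also ended in replicate 2's own list (permutation, adjusted p = 0.0573).

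Distal H3K9ac peaks, 5062 or 19.5% of the replicated list, were counted near genes. The protein-coding genes had a mean of 0.929 distal peaks within 100000 bp, and 10 lists had more than random lists. Hox groups 1 to 8 had a mean of 5.43 (adjusted p = 0.00280, permutation), groups 9 to 11 of 4.30, groups 12 and 13 of 3.50, Notch genes of 3.40, and BMP and Hedgehog genes of 2.85. Wnt genes had 2.69, ureteric genes 2.57 (adjusted p = 0.0152, permutation), nephron progenitors 2.40 (adjusted p = 0.0152, permutation), renal stroma 2.26 (adjusted p = 0.0245, permutation) and housekeeping genes 2.25. Hox genes of 1 cluster count many of the same distal peaks, which the permutation p does not allow for. No test with each distal peak counted once was run. The counts ran from 6 to 10 in the Hoxc cluster and from 3 to 10 in Hoxb. They ran from 1 to 3 in Hoxa, and every Hoxd gene had 1. Within the nephron, ureteric and stromal lists the counts were highest at Pax2 (12), Notch2 (10), Wnt7b (9) and Meis2 (8). Chemosensory receptor genes had fewer, a mean of 0.131 (adjusted p = 0.00280, permutation), and the remaining 17 lists did not pass.

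The single genes with the most distal peaks were Ahdc1 and Cxxc5 (25 each), Trim27 (24), Gse1 (23), Wasf2 (21), Ube2d2a (19), Bahcc1 (18), and Fgr, Ptma and Sept9 (17 each). Ahdc1, Fgr and Wasf2 lie within 1 stretch of chromosome 4, and Cxxc5 and Ube2d2a within 1 stretch of chromosome 18, so that their counts share peaks. Against random lists of genes with a marked promoter, 4 lists had more distal peaks (both Hox lists up to group 11, Notch, and BMP and Hedgehog), and the calls of nephron progenitors (permutation, adjusted p = 0.147), ureteric genes (0.0648), renal stroma (0.0990), Wnt (0.113), housekeeping genes (0.142) and Hox groups 12 and 13 (a mean of 1) ended. In replicate 2's own list nephron progenitors (permutation, adjusted p = 0.0760) and housekeeping genes (0.0705) lost the call, and in replicate 1's own list renal stroma (0.0646), housekeeping genes (0.0939) and Hox groups 12 and 13 (0.106). The pooled list ended the calls of nephron progenitors, renal stroma, Wnt and Hox groups 9 to 13, and a signal value of 4 or more those of nephron progenitors, ureteric genes, renal stroma, housekeeping, Wnt and Notch genes.

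**Figure D4:**
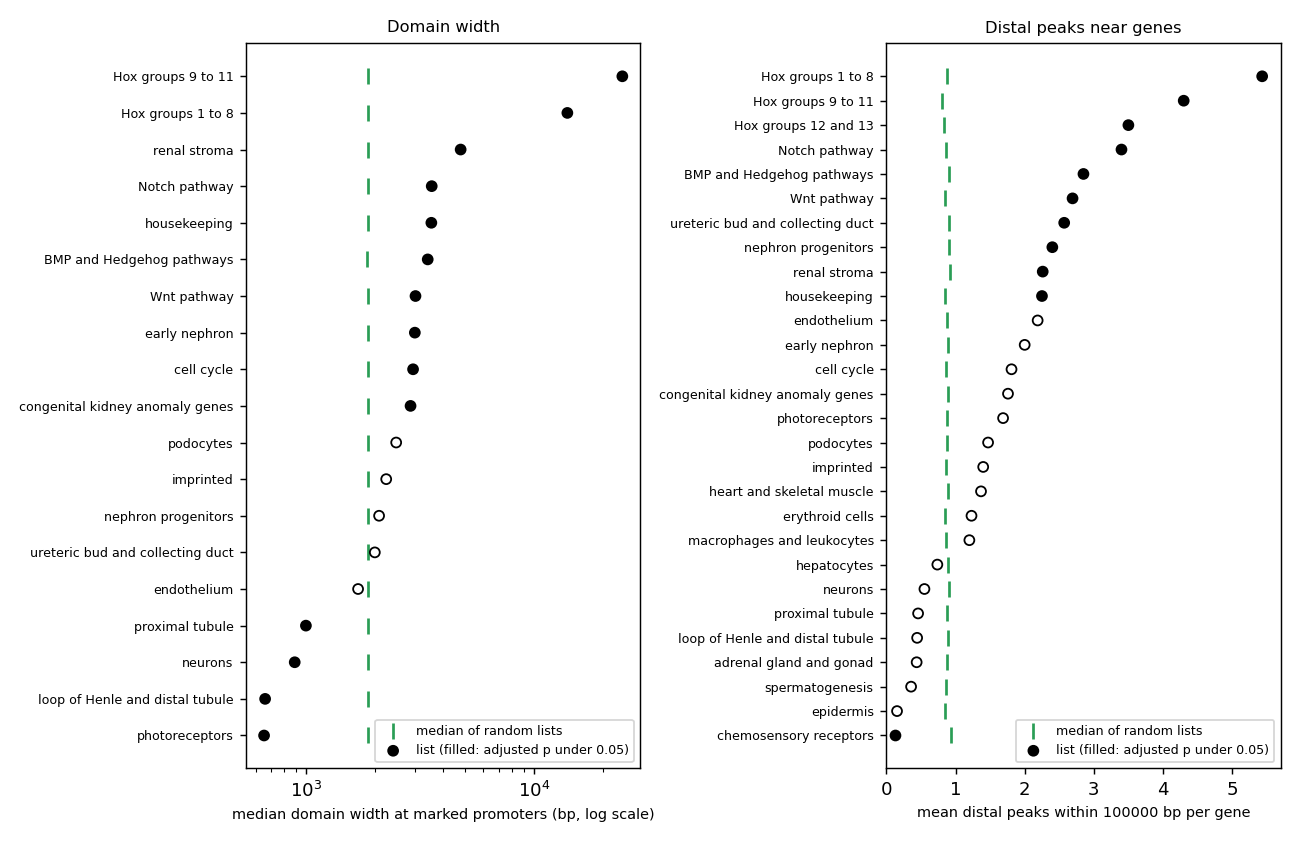
Left, median width of the merged H3K9ac domain at marked promoters of each list (horizontal axis, bp, log scale); right, mean number of distal H3K9ac peaks within 100000 bp of each list's genes. Circles are the lists, filled where the adjusted permutation p was under 0.05, and green bars the median of random lists. With peaks merged within 1000 bp Hox groups 9 to 11 are widest at 24439 bp, and Hox groups 1 to 8 have the most distal peaks, 5.43 per gene.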

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

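No test was run in this part, and the peaks in it were singled out after the data had been seen. The series held 1 group of 2 replicates, so neither outlying samples nor differences between groups were looked for.

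The replicated list held 5 peaks on scaffolds that are not placed within a chromosome. No comparison of genes or locations used this part of the assembly. The 5 peaks were flagged because they passed a limit of 3, which was set by choice and not from an expected count. The strongest lay on scaffold GL456216, assigned to chromosome 4, from 16139 to 17474 (signal value 9.07). Scaffold GL456233, assigned to chromosome X, held 3 of them, at 38628 to 39144 (4.61), 39295 to 39638 (4.37) and 159594 to 160127 (5.78). The fifth lay on the unassigned scaffold JH584304 from 59808 to 60457 (1.80). The genes at these positions were not analysed here.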

How the results depend on the processing

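Restrictions by neighbouring start and unique sequence, overlap at 50% of either peak, domains counted once, chromosome X without chemosensory genes, and CpG matching of widths, distal counts and X were tests chosen after the data had been seen; the rest were fixed beforehand. The depth of the replicates is unknown, which limits any reading of peaks found in 1 of them. No paired analysis was possible because the series held 1 group.

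The lower share of X promoters marked kept its direction and its side of the threshold in all 10 alternatives, and the promoter share of summits stayed above placement in all 6. Merging overlapping peaks moved nothing, since none overlap. Sharing of replicate 1 and replicate 2 peaks became 43.8% and 56.0% with 50% of the peak covered by a single peak. With 50% of both it was 37% and 45.8%, and at a q-value of 0.01 or lower 64.6% and 70.8%. The shares were 87.3% and 82.9% at a signal value of 4 or more, and 59.3% and 61.1% with lists of equal length. Replicated peaks overlapped in both replicates rose from 64.6% to 86.4% at 1 bp and 86.1% at 50% of either peak, by the looser rule itself. Promoters marked in 1 replicate alone became 385 and 543 at a signal value of 4 or more, and 460 and 461 with lists of equal length.

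Against CpG-matched random lists 2 lists were above and 6 below in marking, and the direction turned for podocytes (88.2% against 88.8%) and erythroid genes (30.8% against 23.7%), and for loop of Henle and distal tubule genes (50% against 41.6%), which had not passed before. None of the 3 was past the threshold there. With the pooled list 8 lists had narrower domains, of 23 that could be tested. Lists with more distal peaks fell from 10 to 4 against marked genes, 5 with the pooled list, 4 at a signal value of 4 or more and 6 with CpG-matched lists. Lists with fewer became 0 against marked genes, 2 with the pooled list and 2 without either replicate, and Hox groups 12 and 13 turned to a mean of 1 over their 2 marked genes. Apart from the change of rule noted, the cause was not tested.

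Among single lists, calls on marking also ended outside CpG matching, by exact tests. At a signal value of 4 or more this held for ureteric genes (adjusted p = 0.141, exact) and podocytes (0.0942), and at the outermost start for podocytes (0.0942), imprinted (0.794) and erythroid genes (0.0566). Among unique promoters it held for ureteric (0.145), podocyte (0.192), imprinted (0.105) and erythroid genes (0.147). It also held for Hox genes of groups 9 to 11 (0.0963, all 10 still marked). The ureteric, podocyte and imprinted shares there were 89.5%, 88.2% and 93.3%, and erythroid genes were at 44.4%. The share of the other genes was 71.3% for podocytes there, against 63.1% in the main test. Without neighbouring starts calls ended for imprinted and erythroid genes (0.0631 each), neurons (0.0740) and proximal tubule (0.139). Their shares there were 90%, 30.8%, 36.8% and 40.9%, against 93.3%, 30.8%, 35% and 41.7% in the main test. With the pooled list calls ended for macrophages (0.0577), proximal tubule (0.418) and neurons (0.816). Proximal tubule also lost the call at 500 bp (0.0568) with its share unchanged at 41.7%, neurons at 2500 bp (0.108), and both in each replicate's own list. Over all settings 40 results on marking lost a call with the direction kept and 13 gained one. Endothelium gained a call in 6 settings and loop of Henle genes in 2, both of the latter below. Endothelium gained none at a signal value of 4 or more, at the outermost start, among unique promoters or without neighbouring starts. Of the 283 named genes, 22 were unmarked at the outermost start, among them Ywhaz, Gnas, Egfl7, Coro1a, Aif1, Camk2a, Nrl and Cngb1. In the pooled list 15 unmarked named genes became marked, among them Hoxa13, Shh, Nphs2, Meox1, Elf5, Dcn, Gad1, Gad2, Elavl3, Plvap and Tie1.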

Other observations

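The tests in this part were chosen after the results they bear on had been seen, except the comparison of gene lists with CpG-matched random lists. The tests of shared promoter sequence were added after the patterns were seen, before their own outcome was known.

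Of 8813 intergenic and antisense noncoding genes 1688 (19.2%) had a replicated peak in the promoter window. Where the window lay within 2500 bp of a coding start the share was 59.1%, and elsewhere it was 448 of 6714 (6.67%, Wilson 95% interval 6.10 to 7.29). The highest signals away from coding starts were at 6720427I07Rik (25), Gm27017 (22.5), Gm23925 (20.8), the snoRNA host genes Snhg6 and Snhg12 (19.6 each), Gm8066 (19.6), the microRNA cluster host Mir17hg (19.6), B930059L03Rik (19.3), Gm48623 (19.2) and Malat1 (18.4). The 4 noncoding imprinted genes were all marked, Airn at 10.6, H19 at 8.92, Kcnq1ot1 at 8.19 and Meg3 at 3.80. In the Hox clusters neither Hotair, beside Hoxc11 and Hoxc12, nor Hottip, beside Hoxa13, was marked. Hotair and Hottip were picked after the values were seen, as was Xist below.

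Xist, the noncoding RNA that coats the inactive X chromosome, was marked, with a signal value of 4.68 at 103481822 to 103482959 on chromosome X, as were the Y genes named above. The marked promoters of X were also weaker than those elsewhere. Their median signal value was 7.05 in the replicated list, against 12.2 on the autosomes and 10.4 in autosomal lists matched on CpG content (permutation p = 2e-04, the smallest possible). Within replicate 1's own list the medians were 6.19 and 10.2, and within replicate 2's list 7.01 and 11.1. Signal values were not compared among genes with unique promoter sequence, and the mix of sexes in each pool was not taken into account.

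Fewer promoters were marked on X than on the autosomes, and 3 technical explanations were tested. Promoter CpG content alone would bring X to the 49.4% of CpG-matched autosomal lists, above the 43.2% found (permutation p = 2e-04). Without chemosensory receptor genes the X share was 43.7%, still below 69.4% on the autosomes, so those genes leave the difference in place. Among genes with unique promoter sequence X reached 59.5%, below 71.8%, and below 62.4% in lists of such genes matched on CpG content too (permutation p = 0.0122). Most of the difference in percent may therefore go with shared sequence and CpG content together. Whether the remainder goes with them too cannot be told. Differences in CpG content within a group were not matched, and promoters counted as unique could still share some sequence. No biological explanation was tested, since the series held 1 group with the sexes pooled.

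The lists marked above or below other genes were weighed against features of their promoters. A neighbouring coding start does not account for the lists above, since 12 of the 13 passed without genes that have such a start within 2000 bp. Shared promoter sequence does not account for the lists below, since 10 of the 11 passed among genes with unique promoter sequence. The neuronal call ended in the pooled list and both replicates' own lists (adjusted p = 0.816, 0.380 and 0.243, exact). In the replicated list 5 of the 11 lists below passed against CpG-matched lists, among them neurons and spermatogenesis. Promoter CpG content as divided into 10 groups does not account for these 5. Marking rose from 12.5% in group 3 to 46.1% in group 4 and 86.6% in group 5. Differences in CpG content within a group were not matched and could not be excluded. For the lists above CpG content remains open, since 2 of 13 could have passed with every member marked. For the other 6 lists below, 4 of which could have passed with 0 marked members, CpG content may be a candidate explanation. It cannot be told apart from the tissue there, no biological explanation having been tested.

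Replicated peaks without an overlapping peak in both replicates numbered 3529, and 2 explanations were tested. Of these peaks 83.6% fell in the lowest 25% of the replicated list by signal value, 3.67 or less. Sharing between replicates fell with signal over all peaks, so this outcome was likely beforehand. Low signal may account for the missing overlap of most of these peaks, and leaves open why they were in the replicated list. They were not the weakest peaks called, since their median of 3.12 lay above the 2.55 of pooled peaks that also lacked a peak in both replicates and were not replicated. Peak borders placed differently would need a peak close by in both replicates, and 53.4% had none within 1000 bp in at least 1 replicate. The other 46.6% had a peak within 1000 bp in both, so for them differently placed borders remain possible. A rule for the replicated list that used other divisions of the reads was not tested, and neither was a biological explanation.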
